A study of Homo sapiens with 12 samples.

How the data were processed

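RNA was measured in 12 samples of HaCaT cells, a line of immortalised human keratinocytes, in 4 groups of 3 libraries: Control-siRNA, Control-siRNA+Mix, PHGDH-siRNA and PHGDH-siRNA+Mix. The Mix treatment lasted 24 h per the labels; its contents, the siRNA sequences and whether the libraries of a group came from separate cultures are not given in the sources used here. Per the labels, RNA was taken up in RNAiso Plus and libraries were made with a NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and hg38, without roles, settings or the formula of the values.

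The deposited table holds FPKM, made by the authors, for 58735 genes, with 1 column per sample and no log transformation. The unit was read from the values. In each library, FPKM multiplied by gene length was a whole multiple of 1 step: 100% of the values up to 200 reads lay within 0.05 reads of a whole number. Reads recovered with that step summed to 16403845 to 20901128 per library (mean 18152188). The library size implied by the values was 0.93 to 1.10 times that sum. All 58735 gene identifiers were found in GENCODE 29, of which 58724 had the same start, end and strand. Because 175 symbols were shared by more than 1 identifier, genes were handled by identifier. All 12 sample columns were used. Precision is set by the spread between libraries and, for genes with few reads, by counting error, which PCR duplicates without molecular identifiers can only enlarge.

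The test, the comparisons, 35 gene lists and the rule for naming genes were fixed before the data were examined. A count model had been planned for a count table, with limma on log2(FPKM + 1) planned in its place for FPKM, and the latter was used. Genes with a mean of 0.5 FPKM or more in at least 1 group entered the test (14577 genes). One limma model (trend and robust options) with a mean per group was fitted to all 12 samples, leaving 8 residual degrees of freedom, and p-values were two-sided and Benjamini-Hochberg adjusted over the genes of each comparison, with 0.05 as the threshold. The 5 comparisons were PHGDH siRNA against control siRNA without mix and with mix, mix against no mix in each siRNA arm, and the interaction, which is the mix effect under PHGDH siRNA minus that under control siRNA. Log2 fold changes on this scale understate changes, most of all for genes below about 1 FPKM but also where a group lies at a few FPKM. An exact permutation test of 3 against 3 libraries cannot give a p-value below 0.1.

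Gene lists with 5 or more tested members (31 of 35) were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists. The plan named voom log-CPM as the scale of that test, and log2(FPKM + 1) was used because no counts were at hand. Camera with an estimated correlation and fry were run beside it. Members past the gene test were counted over all genes tested and also adjusted over the list alone. The remaining 4 lists, markers of fibroblasts, melanocytes, leukocytes and endothelial cells, were used to look for other cells.

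Named genes followed a rule. In each comparison of 2 groups these were the 6 largest changes up and the 6 down among genes with a symbol, an adjusted p past the threshold, 1 FPKM or more in a group and no overlap between the groups. For the interaction, 5 up and 5 down by adjusted p were to be named if any passed, and otherwise the 3 with the lowest raw p. Each described list could add up to 4 members past the threshold by adjusted p. A panel of 21 genes was named whatever its result; ASNS, with a mean below 0.5 FPKM in every group, was not tested. Genes chosen otherwise are said to have been chosen after their values were seen.

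Replicate numbers were checked for pairing by correlating each library's deviation from its group mean across genes between same-numbered libraries. Over all groups, 5 of 18 pairs were above 0.1 (lowest -0.387, highest 0.775), so the numbers were not taken as pairs. Within the PHGDH-siRNA arms the 3 pairs gave 0.69, 0.775 and 0.459, so a model with the replicate as a block in those arms is given beside the mix response under PHGDH siRNA and the interaction. Deviations from a mean of 3 libraries are not independent, so a deviation shared by the replicate 2 libraries raises the other correlations too. The values therefore do not show that replicates 1 and 3 are paired. For the siRNA contrast averaged over both mix conditions, a fit on the means of same-numbered libraries, 3 against 3, is given instead. It also averages control libraries by number, although their deviations between the mix conditions gave -0.288, 0.0456 and -0.112.

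Recovery was tested on simulated data made from these libraries, with 67, 67 and 66 genes changed by 1.5, 2 and 4 fold. The changed genes were drawn only from genes with higher mean read counts, and all other genes were left unchanged. Libraries were drawn independently, without the deviation shared by the replicate 2 libraries. The shares therefore do not cover genes with few reads or a response of many genes. For PHGDH siRNA without mix, 4.48%, 43.3% and 87.9% were called, with 4.26% false calls; with mix 8.96%, 40.3% and 86.4%, with 10% false calls. For mix under control siRNA the shares were 13.4%, 53.7% and 86.4%, with 2.86% false calls, and under PHGDH siRNA 8.96%, 41.8% and 92.4%, with 3.06% false calls. Changes of 1.5 fold were therefore mostly out of reach.

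Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, the replicate as a block, a fit of only the groups compared, a 2-fold threshold, an estimated correlation and leaving out each library. Added after the data were seen were median-of-ratios rescaling, limma-voom on recovered reads, a minimum of 10 recovered reads, leaving out same-numbered libraries of both PHGDH-siRNA arms, the block in those arms, the contrast of PHGDH siRNA averaged over both mix conditions and its fit on the means of same-numbered libraries. Software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.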

Results

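RNA was sequenced from 12 samples of HaCaT cells, immortalised human keratinocytes, in 4 groups of 3 libraries. Cells had received control siRNA or siRNA against PHGDH, and each arm was studied without and with a 24 h treatment that the labels call Mix. PHGDH encodes phosphoglycerate dehydrogenase, the enzyme that opens the serine synthesis pathway from a glycolytic intermediate. Between 21348 and 22510 genes per library were above 0, and the reads recovered from the FPKM values came to 16403845 to 20901128 per library. Protein-coding genes took 97.5% to 98.1% of these reads and mitochondrial genes 3.81% to 7.08%. Levels are given as mean FPKM ± SD over 3 libraries per group. Changes are log2 fold changes of FPKM + 1 from limma over 14577 genes, with the standard error (SE) of the change. The p-values measure only the spread between these libraries, because the labels do not say whether they came from separate cultures.

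On the principal components of log2(FPKM + 1), the 6 libraries with mix lay between 23.2 and 38.8 on the first component, which held 43.0% of the variance, and the 6 without mix between -36.9 and -9.09. Replicate 2 of PHGDH-siRNA and replicate 2 of PHGDH-siRNA+Mix lay at 50.0 and 46.3 on the second component (27.7%), and the other 10 libraries between -29.6 and 14.4. These replicate 2 libraries differed from the other libraries of their groups in the same genes: 613 genes were more than 1 log2 unit apart in both arms in the same direction, 287 higher and 326 lower, against 8 genes in the control-siRNA arms. Amino acid response genes (ATF4 targets) were lower in both for 27 of 33 members, cytosolic ribosomal proteins for 44 of 51, immediate early genes for 19 of 22, EGFR ligands and pathway genes for 18 of 21, and epithelial cytokines for 14 of 25. Higher in both were 22 of 35 G2/M genes, 19 of 25 cholesterol synthesis genes, 15 of 21 hypoxia genes, 17 of 24 glycolysis genes and 13 of 19 wound and stress keratins and squamous serpins. Mitochondrial rRNA took 0.740% and 0.708% of the reads in these libraries and 0.249% to 0.359% in the others. All libraries stayed in the tests, and calls without this pair are given for each comparison. Control-siRNA replicate 1 lay at 33.1 on the third component (8.35%), and the other libraries between -15.65 and 12.64. Mitochondrial genes took 7.08% of its reads, against 4.84% and 4.74% in replicates 2 and 3 of Control-siRNA.

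**Figure D1:**
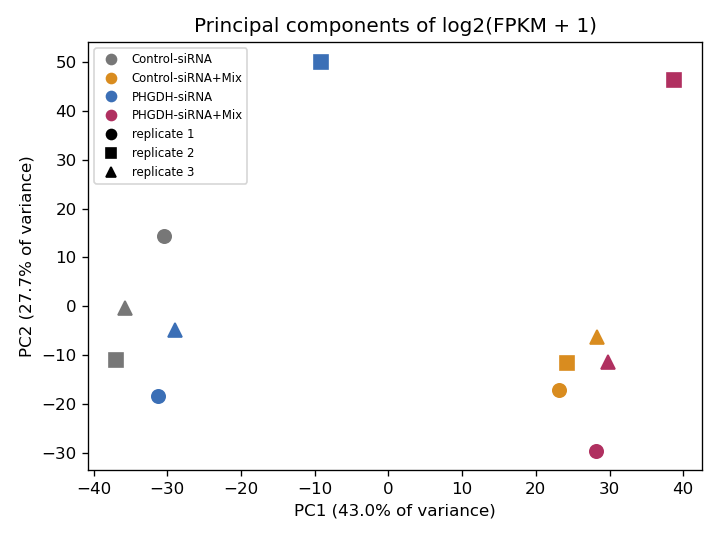
Each point is 1 library on the first (43.0% of variance) and second (27.7%) principal components of log2(FPKM + 1), in arbitrary units, with colours for the 4 groups and shapes for the replicate number. The 6 libraries with mix lie above 23 on the first axis, and replicate 2 of both PHGDH-siRNA arms lies at 50.0 and 46.3 on the second.

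PHGDH (ENSG00000092621, hg38 chromosome 1, 119648411 to 119744226, plus strand) was lower under its siRNA in both mix conditions, with no overlap between groups, but its change passed the test in neither comparison alone. The Control-siRNA libraries held 36.5, 56.2 and 45.8 FPKM and the PHGDH-siRNA libraries 23.7, 20.1 and 16.9 FPKM. With mix, the Control-siRNA+Mix libraries held 31.9, 31.2 and 26.6 FPKM and the PHGDH-siRNA+Mix libraries 19.1, 13.3 and 11.5 FPKM. Means without mix were 46.2 ± 9.84 and 20.2 ± 3.44 FPKM, a 2.28-fold lower level (log2 fold change -1.14, SE 0.207, adjusted p = 0.128). With mix they were 29.9 ± 2.88 and 14.6 ± 3.96 FPKM (-1.01, SE 0.207, adjusted p = 0.2). Averaged over both mix conditions, a contrast added after the data were seen, PHGDH fell by 1.08 on the log2 scale (SE 0.146, adjusted p = 0.0197), a call that did not hold without the filter on low values (adjusted p = 0.056) or with same-numbered libraries averaged (adjusted p = 0.45). Between mix and no mix, PHGDH differed by -0.59 in the control arm (adjusted p = 0.108) and by -0.46 in the PHGDH-siRNA arm (adjusted p = 0.222).

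**Figure D2:**
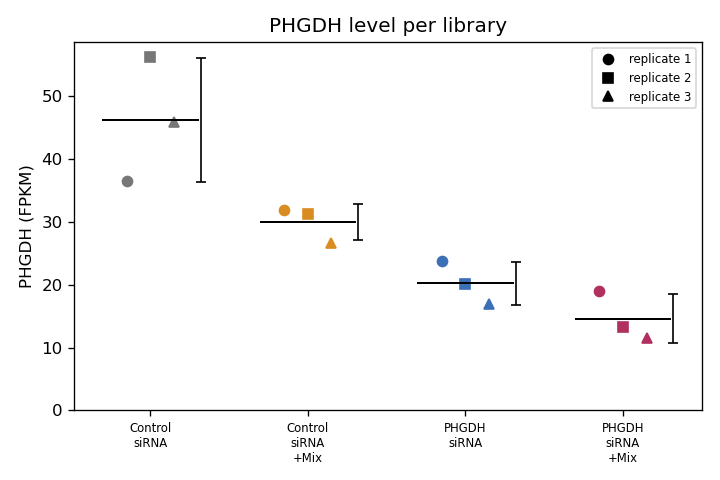
PHGDH level in FPKM (vertical axis) in each of the 12 libraries by group (horizontal axis); points are libraries, lines are group means and the bars beside them are ± SD of 3 libraries. The PHGDH-siRNA libraries lie between 16.9 and 23.7 FPKM and the Control-siRNA libraries between 36.5 and 56.2 FPKM.

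The comparison of PHGDH siRNA with control siRNA without mix asked which transcripts differed in cells not given the mix. SEMA7A, a membrane-anchored semaphorin, rose from 4.51 ± 1.44 to 13.5 ± 1.66 FPKM (log2 fold change 1.42, SE 0.18). ARID3B, a DNA-binding protein, rose from 2.22 ± 0.164 to 4.81 ± 0.131 FPKM (0.85, SE 0.114). Both genes lie on chromosome 15, SEMA7A (ENSG00000138623) at 74409289 to 74433958 and ARID3B (ENSG00000179361) at 74541177 to 74598131. ALDH3A1 (ENSG00000108602), an aldehyde dehydrogenase, fell from 10.4 ± 2.75 to 3.10 ± 0.761 FPKM (-1.46, SE 0.19) and AKR1B10 (ENSG00000198074), an aldo-keto reductase, from 8.11 ± 0.843 to 3.16 ± 0.219 FPKM (-1.13, SE 0.138). PADI3 (ENSG00000142619), which converts arginine to citrulline in proteins of hair and epidermis, fell from 6.57 ± 1.29 to 2.17 ± 0.364 FPKM (-1.25). AGR2 (ENSG00000106541), a disulfide isomerase of the endoplasmic reticulum, fell from 1.63 ± 0.21 to 0.447 ± 0.0611 FPKM (-0.86). These 6 genes, 2 up and 4 down, were all that passed limma (adjusted p = 0.0303 for ARID3B and 0.0295 for the others). With a pseudocount of 0.1 the 4 lowered genes were not called (adjusted p = 0.315 for AKR1B10 and 0.0546 for the others), and with voom AKR1B10 was not (adjusted p = 0.148). None of the 6 was called without the filter on low values (adjusted p = 0.0815 to 0.0943) or with the replicate as a block (adjusted p = 0.106). A fit of these groups alone called none of them either (adjusted p = 0.566). A raw p under 0.05 was found for 935 genes, and 10.2% of genes did not overlap between the groups, where chance gives 10%. Enzymes next to PHGDH in serine synthesis were not called: PSAT1 measured 132 FPKM against 179 (adjusted p = 0.966) and PSPH 23.2 against 28.0 (adjusted p = 0.996). Inflammatory panel genes were not called either, among them CXCL8 at 11.7 ± 8.03 against 3.31 ± 0.783 FPKM (adjusted p = 0.665) and IL36G at 2.65 ± 2.34 against 0.363 ± 0.293 FPKM (adjusted p = 0.512).

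Without mix, 19 of 31 gene lists passed camera, 14 up and 5 down, of which none passed with an estimated correlation (lowest adjusted p = 0.076) and 5 passed fry. Adjusted p-values of camera are given here for the preset and then for the estimated correlation. No member passed over all genes tested except AKR1B10. Epithelial cytokines and chemokines were higher under PHGDH siRNA in 20 of 25 members (median 0.49, adjusted p = 1.68e-05 preset and 0.29 estimated), and 5 rose adjusted over the list alone. NF-kappaB feedback and target genes were higher in 26 of 30 (median 0.25, adjusted p = 1.68e-05 preset and 0.076 estimated), with 2 up adjusted over the list alone. The same direction was found for JAK-STAT3 targets (17 of 21 higher, median 0.25, adjusted p = 0.00093 preset and 0.0946 estimated). It was also found for p53 targets (17 of 23 higher, median 0.31, adjusted p = 0.0012 preset and 0.076 estimated) and extracellular matrix genes (24 of 31 higher, median 0.17, adjusted p = 0.00053 preset and 0.0914 estimated). NRF2 and glutathione genes, which handle oxidants, were lower in 23 of 27 (median -0.23, adjusted p = 0.000134 preset and 0.29 estimated), and AKR1B10 was the member that fell. Histone transcripts were lower in 9 of 12 (median -0.45, adjusted p = 0.00145 preset and 0.515 estimated), as they were in 9 of 12 in both replicate 2 libraries. Mitochondrially encoded mRNAs were lower in 12 of 13 (median -0.24, adjusted p = 0.00136 preset and 0.365 estimated), but not called without Control-siRNA replicate 1 (adjusted p = 0.214). Immediate early genes were higher in 19 of 22 (median 0.37, adjusted p = 0.000134 preset and 0.515 estimated) and EGFR ligands and pathway genes in 16 of 21 (median 0.32, adjusted p = 0.000362 preset and 0.515 estimated). Both lists, low in the replicate 2 libraries, lost their calls without PHGDH-siRNA replicate 1 (adjusted p = 0.281 and 0.0872). The other 9 called lists had medians of -0.13 to 0.41, and each lost its call without at least 1 library. Hypoxia genes (median 0.21) stood at -0.02 and stress keratins (median 0.41) at 0.01 without PHGDH-siRNA replicate 2, in which both were high. With a single library left out and the call kept, the NF-kappaB median moved to 0.12 and the NRF2 median to -0.12 without PHGDH-siRNA replicate 2. The cytokine median moved to 0.25 and the p53 median to 0.17 without PHGDH-siRNA replicate 1, and the p53 median to 0.21 without Control-siRNA replicate 1. The extracellular matrix median moved to 0.26 without Control-siRNA replicate 2. Serine synthesis and folate cycle genes did not pass (18 members, median -0.02, adjusted p = 0.399), nor did ATF4 targets (adjusted p = 0.0695), purine synthesis (adjusted p = 0.923) or the RNA interference machinery (adjusted p = 0.413).

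Call counts for PHGDH siRNA without mix depended on single libraries. Limma called 4 genes without Control-siRNA replicate 1, 1 gene without Control-siRNA replicate 2 or PHGDH-siRNA replicate 1, and 0 genes without Control-siRNA replicate 3, PHGDH-siRNA replicate 2 or PHGDH-siRNA replicate 3. The gene called without PHGDH-siRNA replicate 1 was not among the 6 (adjusted p = 0.079 to 0.175 for those). Without replicate 2 of both PHGDH-siRNA arms, 101 genes were called (51 up, 50 down), including all 6, and among those gained CXCL8 rose by 1.83 (adjusted p = 0.031).

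Under mix, the comparison of PHGDH siRNA with control siRNA asked which transcripts of treated cells differed. SEMA7A rose again, from 11.9 ± 0.543 to 41.5 ± 6.69 FPKM (log2 fold change 1.71, SE 0.18, adjusted p = 0.0191), and so did ARID3B, from 4.16 ± 0.132 to 8.77 ± 1.31 FPKM (0.91, adjusted p = 0.0321). ACOD1 (ENSG00000102794), which makes itaconate from a citric acid cycle intermediate, fell from 7.47 ± 0.953 to 2.66 ± 0.723 FPKM (-1.22, SE 0.149, adjusted p = 0.0321). S100A7, an antimicrobial protein of inflamed epidermis (ENSG00000143556, chromosome 1, 153457744 to 153460701), was at 137 ± 38.1 against 359 ± 33.3 FPKM without overlap between the groups. It did not pass (-1.42, SE 0.208, adjusted p = 0.0745, and 0.0342 to 0.456 over the alternatives). ACOD1 was not called with voom (adjusted p = 0.189), nor with a pseudocount of 0.1 (adjusted p = 0.298), where ARID3B was not called either (adjusted p = 0.062). Without the filter on low values ACOD1 and ARID3B were not called (adjusted p = 0.0518 for both). None of the 3 called genes was called with the replicate as a block (adjusted p = 0.108) or in a fit of these groups alone (adjusted p = 0.456 for ACOD1 and ARID3B and 0.102 for SEMA7A). The related S100A8 (263 against 460 FPKM, adjusted p = 0.494) and S100A9 (2021 against 3195 FPKM, adjusted p = 0.979) were not called. IL36G, a cytokine of keratinocytes, was at 84.0 ± 32.5 against 31.1 ± 3.5 FPKM (adjusted p = 0.591), and was called without the replicate 2 pair (1.65, adjusted p = 0.0272). Limma called 3 genes, 2 up and 1 down, with 834 at a raw p under 0.05 and 14.3% of genes without overlap (chance 10%). Leaving out Control-siRNA+Mix replicate 1 or 2 gave 0 calls. Leaving out Control-siRNA+Mix replicate 3 gave 1, another gene than these 3 (adjusted p = 0.0969 for SEMA7A, 0.211 for ACOD1 and 0.254 for ARID3B). Leaving out PHGDH-siRNA+Mix replicate 2 gave 6 calls and replicate 3 gave 5. Without replicate 2 of both PHGDH-siRNA arms 55 genes were called, including all 3.

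With mix, 10 of 31 lists passed camera, 3 up and 7 down, of which none passed with an estimated correlation (lowest adjusted p = 0.23), and 0 lists passed fry. DNA replication and S phase genes were lower under PHGDH siRNA in 38 of 42 members (median -0.28, adjusted p = 3.83e-12 preset and 0.299 estimated). G2/M genes were lower in 30 of 35 (median -0.32, adjusted p = 3.24e-09 preset and 0.464 estimated), but not called without PHGDH-siRNA+Mix replicate 1 (adjusted p = 0.0593). No member of either list passed over all genes, and 1 G2/M gene fell adjusted over the list alone. G2/M genes were high in the replicate 2 libraries. Without that pair the G2/M median was -0.54 and that of the DNA replication list -0.40 (adjusted p = 0.0137 estimated). Cytokines were lower in 15 of 25 (median -0.48, adjusted p = 0.01 preset and 0.642 estimated), with 7 down and 1 up adjusted over the list alone. Their median was -0.07 without PHGDH-siRNA+Mix replicate 2, in which they were low (adjusted p = 0.288). For antimicrobial peptides the median was 0.01 and the mean -0.21, and camera read the list as down (adjusted p = 0.01 preset and 0.434 estimated), with 4 of 15 down adjusted over the list alone. That call was lost without the same library (adjusted p = 0.238). Extracellular matrix genes were higher in 21 of 31 (median 0.12, adjusted p = 0.00165 preset and 0.23 estimated), 5 of them up adjusted over the list alone. Targets of p53 were higher in 18 of 23 (median 0.20, adjusted p = 0.0198 preset and 0.23 estimated), but not called without PHGDH-siRNA+Mix replicate 1 (adjusted p = 0.176). The serine synthesis and folate cycle list was lower in 12 of 18 (median -0.16, adjusted p = 0.0435 preset and 0.299 estimated) and stood at 0.04 without PHGDH-siRNA+Mix replicate 2 (adjusted p = 0.275). It also lost its call without Control-siRNA+Mix replicate 1 or 2 or PHGDH-siRNA+Mix replicate 3 (adjusted p = 0.0814, 0.058 and 0.0756). Adjusted over the list alone 1 member fell. Whether the list would be called without PHGDH, the gene that the siRNA targets, was not tested. Basal keratinocyte genes (median 0.18, adjusted p = 0.0132), nuclear oxidative phosphorylation genes (median -0.13, adjusted p = 0.01) and histones (median -0.34, adjusted p = 0.0238) were called as well. All 3 calls were lost without PHGDH-siRNA+Mix replicate 2 (adjusted p = 0.237, 0.0768 and 0.719).

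Gene lists were also tested without replicate 2 of both PHGDH-siRNA arms, a choice made after the data were seen. For PHGDH siRNA without mix 15 lists were called, 12 of them among the 19 above, and with mix 10 were called, 4 of them among the 10 above. Without mix, ATF4 targets were gained (median 0.32 against 0.14 with all libraries, adjusted p = 1.84e-05 preset and 0.469 estimated), as were cholesterol synthesis genes (-0.28 against -0.10, adjusted p = 3.62e-08 preset and 0.266 estimated) and fatty acid synthesis genes (-0.12, adjusted p = 0.0173 preset). Immediate early genes stood at 0.64 (adjusted p = 2.11e-09 preset) and EGFR genes at 0.64 (adjusted p = 1.15e-10 preset). With mix, ATF4 targets (0.21 against -0.04, adjusted p = 0.00106 preset and 0.686 estimated), EGFR genes (0.43, adjusted p = 9.27e-07) and immediate early genes (0.36, adjusted p = 7.74e-05) were gained. Cholesterol synthesis (-0.12, adjusted p = 0.00856), hypoxia (-0.16, adjusted p = 0.0164) and interferon-stimulated genes (-0.08, adjusted p = 0.0243) were gained as well. With an estimated correlation 0 lists passed without mix and 1 with mix, the DNA replication list.

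Averaged over both mix conditions, the contrast added after the data were seen, PHGDH siRNA gave 71 calls (37 up, 34 down, and 1627 at a raw p under 0.05) with the 12 libraries taken as independent. The replicate 2 libraries of the PHGDH-siRNA arms deviated together. With the mean of each same-numbered pair as 1 value, control pairs included, limma called 0 genes (812 at a raw p under 0.05, smallest adjusted p = 0.207, 4 residual degrees of freedom). The adjusted p-values that follow are those with 12 libraries, and none of these genes was called on the means. Examples chosen after their values were seen include SLC2A3, a glucose transporter, which rose from 2.16 to 7.72 FPKM without mix and from 6.4 to 18.4 FPKM with mix (1.37, adjusted p = 0.0197). CD274, the gene of the immune checkpoint ligand PD-L1, rose from 1.02 to 2.21 and from 3.86 to 8.16 FPKM (0.78, adjusted p = 0.0197). SSRP1, a histone chaperone subunit, fell from 73.9 to 44.0 and from 52.2 to 30.3 FPKM (-0.75, adjusted p = 0.00608), and CDCA8, a mitotic chromosome protein, from 42 to 24.2 and from 28.3 to 14.4 FPKM (-0.86). All 71 genes were among the 492 called without replicate 2 of both PHGDH-siRNA arms. The count lay between 2 and 96 when 1 library was left out. Across all 14577 genes the siRNA effects without and with mix had r = 0.478, and r = 0.172 without PHGDH-siRNA replicate 2. Genes are not independent replicates.

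In control-siRNA cells, mix against no mix asked how the keratinocytes responded to the treatment. S100A9 (ENSG00000163220), a subunit of calprotectin, rose from 9.07 ± 4.75 to 3195 ± 214 FPKM (352-fold, log2 fold change 8.41, SE 0.398, adjusted p = 4.78e-07), and its partner S100A8 from 1.33 ± 0.629 to 460 ± 19.4 FPKM (7.66, SE 0.229, adjusted p = 1.79e-08). PI3, the elastase inhibitor elafin, rose from 3.06 ± 2.32 to 1012 ± 95.9 FPKM (8.10) and S100A7 from 0.923 ± 0.285 to 359 ± 33.3 FPKM (7.55, adjusted p = 1.49e-08). The squamous serpins SERPINB4 and SERPINB3 rose from 1.39 to 381 FPKM (7.34) and from 1.68 to 294 FPKM (6.80). Of the genes that fell most, ALPP, a placental alkaline phosphatase, went from 24.1 ± 2.91 to 0.591 ± 0.0656 FPKM (-3.97) and the transcription factor FOXQ1 from 33.7 ± 10.3 to 3.82 ± 0.328 FPKM (-2.80). The keratin KRT13 fell from 107 ± 40.8 to 7.38 ± 0.712 FPKM (-3.62), a call that was lost without Control-siRNA replicate 3 (-3.37, adjusted p = 0.0531). AC068580.2 (-2.61), METTL7A (-2.60) and ALDH3A1 (-2.60) also fell. In all, 1391 genes passed limma, 819 up and 572 down, of which 349 and 124 changed at least 2-fold. Between the groups 37.8% of genes did not overlap (chance 10%). The count was 658 without Control-siRNA+Mix replicate 3 and 3023 without replicate 2 of both PHGDH-siRNA arms, which includes all 1391. Those replicate 2 libraries are no part of this comparison and enter it through the variance per gene, which was fitted over all 12 libraries.

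Under control siRNA, antimicrobial peptides and epithelial cytokines had the highest list medians under mix, again with the adjusted p of camera for the preset and then the estimated correlation. Epithelial cytokines and chemokines rose in 19 of 25 members and 6 did not pass (21 rose adjusted over the list alone, median 2.51, adjusted p = 5.8e-25 preset and 0.00795 estimated). Among them IL24 went from 0.12 to 95.4 FPKM (6.43) and CSF3, a growth factor for neutrophils, from 0.0167 to 46.6 FPKM (5.54). IL1A rose from 10.6 to 266 FPKM (4.56) and the neutrophil attractant CXCL8 from 3.31 ± 0.783 to 224 ± 35.0 FPKM (5.71, adjusted p = 4.62e-05). Antimicrobial peptides rose in 10 of 15, and 5 did not pass (11 up and 1 down adjusted over the list alone, median 3.30, adjusted p = 3.77e-15 preset and 0.00659 estimated). They included LCN2 from 48.4 to 1168 FPKM (4.59) and DEFB4A from 0.145 to 32.8 FPKM (4.87). NF-kappaB feedback and target genes rose in 21 of 30 and fell in 1 (median 1.31, adjusted p = 2.08e-21 preset and 0.00174 estimated), among them SOD2 (3.69 to 84.4 FPKM) and NFKBIZ (2.09 to 15.03 FPKM). JAK-STAT3 targets rose in 13 of 21 (15 adjusted over the list alone, median 1.06, adjusted p = 2.69e-11 preset and 0.00334 estimated), with the feedback inhibitor SOCS3 going from 4.30 to 61.0 FPKM. Wound and stress keratins and squamous serpins rose in 12 of 19 and fell in 1, AKR1B10 (17 up adjusted over the list alone, median 1.85, adjusted p = 9.96e-14 preset and 0.0228 estimated). KRT6A rose from 333 to 1031 FPKM, and KRT16 at 24.5 against 6.52 FPKM did not pass (adjusted p = 0.151). Unfolded protein response genes rose in 5 of 22 (10 adjusted over the list alone, median 0.46, adjusted p = 7.54e-08 preset and 0.00334 estimated). These were the 6 lists that held with an estimated correlation, of 22 called (15 up, 7 down), and 22 passed fry. Without the replicate 2 pair of the PHGDH-siRNA arms 26 lists were called, including all 22, and 10 with an estimated correlation.

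Genes of DNA replication and mitosis fell with mix under control siRNA. DNA replication and S phase genes fell in 24 of 42 and rose in 0 (31 fell adjusted over the list alone, median -0.61, adjusted p = 4.82e-19 preset and 0.0602 estimated). MCM3, part of the replicative helicase, fell from 58.6 ± 2.58 to 27.4 ± 1.55 FPKM (-1.07) and E2F2 from 4.0 to 1.15 FPKM (-1.21). G2/M genes fell in 12 of 35 (median -0.42, adjusted p = 2.57e-08 preset and 0.244 estimated), including FOXM1 from 46.3 to 26.2 FPKM and CCNB1 from 163 to 98.4 FPKM, whereas MKI67 did not pass (adjusted p = 0.773). Serine synthesis and folate cycle genes fell in 4 of 18 (6 adjusted over the list alone, median -0.07, adjusted p = 0.0235 preset and 0.134 estimated), led by MTHFD1, a folate enzyme, from 18.8 to 10.9 FPKM (-0.73). PSAT1, PSPH, SHMT2 and MTHFD2 did not pass (adjusted p = 0.972, 0.615, 0.731 and 0.558). Purine synthesis genes were called down with 0 of 12 past the test over all genes and 3 adjusted over the list alone (adjusted p = 0.000621 preset and 0.113 estimated). Nuclear oxidative phosphorylation genes fell in 5 of 39 (adjusted p = 0.000206 preset and 0.338 estimated) and NRF2 and glutathione genes in 6 of 27 (adjusted p = 0.00666 preset and 0.334 estimated). Mitochondrially encoded mRNAs were called down as well (adjusted p = 0.00212 preset and 0.233 estimated).

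Basal keratinocyte and hemidesmosome genes rose with mix in 9 of 22 (13 adjusted over the list alone, median 0.69, adjusted p = 7.54e-08 preset and 0.0644 estimated). Hypoxia genes rose in 8 of 21 (15 up and 1 down adjusted over the list alone, median 0.90, adjusted p = 5.62e-09 preset and 0.113 estimated), including ANGPTL4 from 6.13 to 74.2 FPKM (3.41). Extracellular matrix genes rose in 9 of 31 and fell in 2 (adjusted p = 5e-04 preset and 0.0507 estimated), and glycolysis genes rose in 6 of 24 (adjusted p = 1.82e-05 preset and 0.215 estimated). EGFR ligands and pathway genes rose in 6 of 21 (adjusted p = 0.00101 preset and 0.338 estimated), and interferon-stimulated genes rose in 9 of 39 and fell in 1 (adjusted p = 0.000135 preset and 0.147 estimated). Called up with few members were ATF4 targets (2 of 33 rose, adjusted p = 0.00666 preset and 0.483 estimated), immediate early genes (4 of 22 rose, adjusted p = 0.00666 preset and 0.483 estimated) and antigen presentation (2 of 19 rose, adjusted p = 0.016 preset and 0.334 estimated). The last was not called without Control-siRNA replicate 1 (adjusted p = 0.228). Epidermal differentiation genes went both ways, with 6 up, 5 down and 28 not passing (adjusted p = 0.251). IVL, a cornified envelope protein, fell from 4.31 to 1.15 FPKM (-1.27, adjusted p = 0.00352) and KRT10 did not pass (adjusted p = 0.906). Lists that did not pass camera were methionine cycle (adjusted p = 0.251), sphingolipid and phospholipid synthesis (0.251), cholesterol synthesis (0.121), fatty acid synthesis (0.0677), cytosolic ribosomal proteins (0.0639), histones (0.058), p53 targets (0.058) and the RNA interference machinery (0.578).

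**Figure D3:**
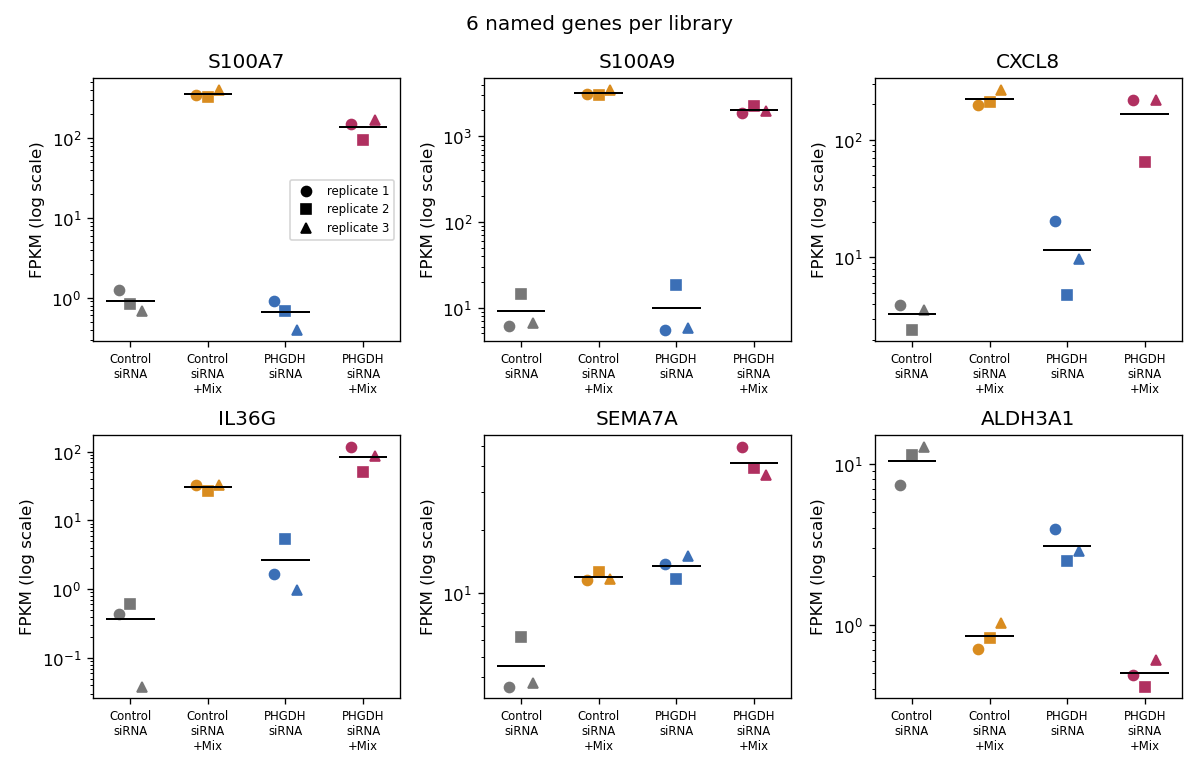
FPKM on a log axis (vertical) for S100A7, S100A9, CXCL8, IL36G, SEMA7A and ALDH3A1 in each of the 12 libraries by group (horizontal); points are libraries and lines are group means. S100A9 means are 9.07 and 9.91 FPKM without mix and 3195 and 2021 FPKM with mix, and SEMA7A means are 4.51 and 13.5 FPKM without mix and 11.9 and 41.5 FPKM with mix, for control and PHGDH siRNA.

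In PHGDH-siRNA cells, mix against no mix asked how the cells responded to the treatment after PHGDH siRNA. S100A9 rose from 9.91 ± 7.38 to 2021 ± 188 FPKM (log2 fold change 7.73, SE 0.398) and PI3 from 9.27 ± 6.30 to 1703 ± 1121 FPKM (7.24, SE 0.598). S100A8 rose from 1.15 ± 0.713 to 263 ± 30.2 FPKM (6.99), IL24 from 0.263 ± 0.0897 to 143 ± 47.5 FPKM (6.77), S100A7 from 0.661 ± 0.251 to 137 ± 38.1 FPKM (6.35) and SERPINB4 from 6.91 ± 10.0 to 302 ± 121 FPKM (6.0). S100A12, another S100 gene, was listed at 0 in the PHGDH-siRNA libraries and at 9.78 ± 2.10 FPKM with mix. ALPP fell from 20.9 ± 6.38 to 0.893 ± 0.465 FPKM (-3.52) and OLFML2A from 13.6 ± 2.31 to 2.25 ± 1.21 FPKM (-2.22). ID3, an inhibitor of basic helix-loop-helix factors, fell from 107 ± 37.1 to 24.5 ± 5.42 FPKM (-2.05). KRT13 fell (-2.99), and the call was lost without PHGDH-siRNA+Mix replicate 1 (-2.66, adjusted p = 0.0911) or 3 (-2.69, adjusted p = 0.108). FOXQ1 fell (-2.41), and the call was lost without PHGDH-siRNA replicate 1 (-2.04, adjusted p = 0.0697) or 3 (-2.08, adjusted p = 0.0778). KRT80 fell (-2.0), and the call was lost without PHGDH-siRNA replicate 1 or 3 (-1.64 and -1.77, adjusted p = 0.0862 and 0.0971) or PHGDH-siRNA+Mix replicate 2 or 3 (-1.58 and -2.09, adjusted p = 0.0538 and 0.0589). Limma called 1291 genes, 761 up and 530 down, of which 302 and 102 changed at least 2-fold, and 21.5% of genes did not overlap (chance 10%). With the replicate as a block in these arms 3284 genes were called, including all 1291. A fit of these 6 libraries alone called 254, leaving out PHGDH-siRNA replicate 3 left 665, and leaving out replicate 2 of both arms gave 2190, of which 1191 were shared.

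Under PHGDH siRNA, cytokines rose with mix in 16 of 25 and 9 did not pass (21 up and 1 down adjusted over the list alone, median 1.52, adjusted p = 3.71e-18 preset and 0.0216 estimated). Antimicrobial peptides rose in 9 of 15 (11 adjusted over the list alone, median 2.83, adjusted p = 9.31e-15 preset and 0.00719 estimated). NF-kappaB genes rose in 16 of 30 and fell in 1 (median 1.03, adjusted p = 1.81e-17 preset and 0.00376 estimated), and JAK-STAT3 targets rose in 12 of 21 (median 0.93, adjusted p = 7.58e-10 preset and 0.00557 estimated). CXCL8 rose from 11.7 ± 8.03 to 167 ± 89.0 FPKM (3.74), SOD2 from 4.36 to 77.3 FPKM (3.86) and SOCS3 from 6.01 to 46.6 FPKM (2.76). Wound and stress keratins and squamous serpins rose in 12 of 19 and fell in 1 (median 1.58, adjusted p = 5.3e-12 preset and 0.0295 estimated), among them KRT6B from 0.589 to 49.4 FPKM. Unfolded protein response genes rose in 5 of 22 (median 0.44, adjusted p = 1.01e-07 preset and 0.00448 estimated). Extracellular matrix genes rose in 9 of 31 and fell in 1 (median 0.48, adjusted p = 0.000473 preset and 0.0414 estimated). DNA replication and S phase genes fell in 31 of 42 (35 down and 1 up adjusted over the list alone, median -0.87, adjusted p = 4.83e-26 preset and 0.0295 estimated), with MCM3 going from 53.1 to 23.1 FPKM (-1.17). G2/M genes fell in 15 of 35 (median -0.59, adjusted p = 3.72e-12 preset and 0.178 estimated). Basal keratinocyte genes rose in 10 of 22 (median 0.56, adjusted p = 3.31e-08 preset and 0.0507 estimated) and hypoxia genes in 5 of 21, with 1 down (median 0.57, adjusted p = 1.16e-06 preset and 0.178 estimated). Serine synthesis and folate cycle genes fell in 5 of 18 (median -0.20, adjusted p = 0.00255 preset and 0.0507 estimated). In all, 20 lists were called (14 up, 6 down), 18 by fry, 8 with an estimated correlation, and 4 with an estimated correlation in the blocked model. Without the replicate 2 pair 19 lists were called, 18 of them shared, and 8 with an estimated correlation. Interferon-stimulated genes (adjusted p = 0.00381), EGFR genes (0.00997), histones (0.0222), cholesterol synthesis (0.0174) and ribosomal proteins (0.0186) each lost the call without at least 1 library and with an estimated correlation (adjusted p = 0.311, 0.488, 0.47, 0.5 and 0.686). For ribosomal proteins the median changed sign, to 0.0291, without PHGDH-siRNA+Mix replicate 2.

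The mix responses of both siRNA arms overlapped: 601 genes rose in both, where independent calls would give 42.8, and 358 fell in both, where they would give 20.8. Both arms were fitted in the same model with a shared variance per gene, so their calls are not independent. The expected counts are therefore no test of the overlap. Of the genes that rose under control siRNA, 814 of 819 had the same sign under PHGDH siRNA, as did 566 of 572 that fell. Across 14577 genes the mix effects had r = 0.87, and r = 0.959 over the 1723 called in either arm.

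**Figure D4:**
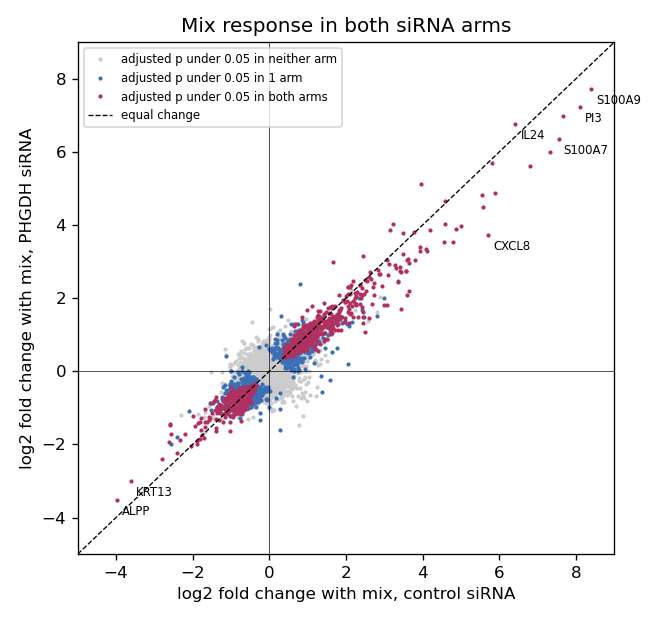
Log2 fold change of FPKM + 1 with mix under control siRNA (horizontal axis) and PHGDH siRNA (vertical axis), 1 point per gene of 14577, grey if called in neither arm, blue in 1 and crimson in both; the dashed line marks equal change. The points follow the line (r = 0.87 across genes), with 601 genes up and 358 down in both arms.

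The interaction asked whether the response to mix differed between the siRNA arms. Limma called 0 genes (smallest adjusted p = 1), with 250 at a raw p under 0.05, voom called 0 and a fit without the filter on low values called 5 (2 up, 3 down). The blocked model called 0 as well (561 at a raw p under 0.05, smallest adjusted p = 0.161). The 3 genes with the lowest raw p were ACOD1 (-1.26, SE 0.211), AGR2 (0.78, SE 0.157) and the cytokine TNF (-1.12, SE 0.224). Without mix ACOD1 was at 0 and 0.0277 FPKM under control and PHGDH siRNA, so its difference mostly repeats that between the groups with mix. Group means of AGR2 lay between 0.305 and 1.63 FPKM, where this log scale understates changes. In the panel, the lowest difference was that of CXCL8 (-1.97, SE 0.717) and the highest that of IVL (0.31, SE 0.302), both chosen from the panel after their values were seen. Among 471 genes that responded to mix at least 2-fold on average, the response under PHGDH siRNA was smaller for 71.1% of 360 raised and 71.2% of 111 lowered genes. The slope of the difference on the response was -0.133 (jackknife SE 0.103). It was -0.0518 without PHGDH-siRNA replicate 2 and -0.0372 without replicate 2 of both arms. In a single draw of simulated independent libraries with no difference it was -0.0322, a value without a spread.

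Of 31 lists, 10 passed camera for the interaction, 1 up and 9 down, of which none passed with an estimated correlation (lowest adjusted p = 0.0718), and 0 lists passed fry. Without the filter on low values 5 lists were called. Cytokines differed by a median of -0.82, lower in 19 of 25 (adjusted p = 3.84e-15 preset and 0.0854 estimated, 4 down adjusted over the list alone). Without replicate 2 of both PHGDH-siRNA arms, in which the list was low, the median was -0.405 and the list was still called at the preset correlation (adjusted p = 4.79e-07 preset and 0.16 estimated). NF-kappaB genes differed by -0.24, lower in 25 of 30 (adjusted p = 2.7e-07 preset and 0.0718 estimated, 1 down adjusted over the list alone), and by -0.16 without the pair. DNA replication and S phase genes differed by -0.21, lower in 39 of 42 (adjusted p = 1.2e-07 preset and 0.56 estimated). Without the replicate 2 pair they differed by -0.34 (adjusted p = 1.06e-19 preset and 0.0268 estimated), the only list past the threshold with an estimated correlation in that fit. Antimicrobial peptides differed by -0.55, lower in 11 of 15 (adjusted p = 5.91e-05 preset and 0.222 estimated, 2 down adjusted over the list alone). They differed by -0.40 without PHGDH-siRNA replicate 2 alone (adjusted p = 0.118) and by -0.05 without the replicate 2 pair (adjusted p = 0.165). G2/M genes differed by -0.18 (adjusted p = 0.000858 preset and 0.708 estimated), by 0.02 without PHGDH-siRNA+Mix replicate 1 and by -0.40 without the replicate 2 pair. JAK-STAT3 targets (median -0.08, adjusted p = 0.0125), stress keratins (-0.23, 0.0125), hypoxia genes (-0.20, 0.0107), NRF2 and glutathione genes (0.11, 0.0113) and immediate early genes (-0.21, 0.0171) were called too. Each of these lost its call without at least 1 library. Without the replicate 2 pair 12 lists were called, 8 of them among the 10, and limma called 0 genes. In the blocked model 16 lists were called (3 up, 13 down) and 0 with an estimated correlation (lowest adjusted p = 0.0731).

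Markers of other cells stayed low in all libraries. The highest values were 1.44 FPKM for COL1A1 among 11 fibroblast markers, 0.731 FPKM for PMEL among 8 melanocyte markers, 3.92 FPKM for LAPTM5 among 20 leukocyte markers and 0.903 FPKM for VWF among 10 endothelial markers.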

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

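In this part the regroupings and splits of single libraries were planned, and the tests of left-out library pairs and of the pseudocount, the average siRNA contrast and the tests that keep libraries in pairs were chosen only after the results were seen.

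For 10 gene lists the test of the difference between the mix responses of the 2 siRNA arms passed camera, which is what picked them out. The median difference was -0.549 for antimicrobial peptides, -0.816 for epithelial cytokines and chemokines, -0.244 for NF-kappaB genes and -0.081 for JAK-STAT3 targets. It was -0.229 for wound and stress keratins and squamous serpins, -0.198 for hypoxia genes and -0.213 for immediate early genes. For the cell cycle it was -0.181 for G2/M genes and -0.214 for DNA replication and S phase genes, and for NRF2 and glutathione genes it was 0.108. With all 12 libraries none of the 10 passed with an estimated correlation, and without the replicate 2 pair DNA replication and S phase genes did (median -0.341, adjusted p = 0.0268).

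TNF and SOCS1, a feedback inhibitor of cytokine signalling, were picked out because PHGDH siRNA moved every library one way without mix and the opposite way with mix. TNF was at 1.24 ± 0.207 against 0.484 ± 0.322 FPKM without mix and at 4.64 ± 0.496 against 7.02 ± 0.583 FPKM with mix, a log2 difference of -1.12. SOCS1 was at 1.97 ± 1.03 against 1.12 ± 0.213 FPKM without mix and at 18.01 ± 2.77 against 21.9 ± 0.596 FPKM with mix, a log2 difference of -0.717. The difference was not tested by the rule that picked them, and neither gene passed the interaction of limma (adjusted p = 1 for both).

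Among 471 genes that responded at least 2-fold, the response to mix was smaller on average under PHGDH siRNA (slope -0.133, jackknife SE 0.103), whereas DNA replication and G2/M lists fell more (medians -0.866 and -0.595 against -0.611 and -0.421). With all libraries neither list difference passed at the estimated correlation. The median G2/M difference ranged from -0.404 to 0.0198 with 1 library left out, the latter without PHGDH-siRNA+Mix replicate 1. A floor of the log scale is argued against, because the slope was -0.125 with a pseudocount of 0.1. Replicate 2 of both PHGDH-siRNA arms is a candidate cause for the slope, which was -0.0372 without the pair. Simulated data with no difference gave -0.0322, but in a single draw of independent libraries with no pair left out. The simulated mix response also started from the mean over all libraries, not from the levels without mix. That value therefore has no spread and decides nothing about the pair. For the cytokine list the pair remains open as a cause, since without it the median of -0.816 moved to -0.405 and the call held at the preset correlation (adjusted p = 4.79e-07), while at the estimated one the list was called neither with nor without the pair (adjusted p = 0.0854 and 0.16). An effect of PHGDH siRNA stays open.

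PHGDH siRNA gave few calls, 6 without and 3 with mix, and the spread that the replicate 2 libraries add may be why. Without both of them 101 genes were called in cells without mix, against 1 and 0 without both replicate 1 or both replicate 3 libraries. The pair was picked because it deviates, so leaving it out lowers the fitted spread by construction. Mix under control siRNA, a comparison without these libraries, also went from 1391 to 3023 calls. The added calls are therefore not shown to be effects of PHGDH siRNA. Splits of 6 libraries number 10, too few for a share under 0.05: the real counts of 6 and 3 genes compare with 2 and 2 at most in another split, and those of 19 and 10 lists with 16 and 10, the latter reached by 2 of the 10 splits.

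Regroupings of the siRNA labels within each mix condition took all libraries as independent, although the replicate 2 libraries of the PHGDH-siRNA arms deviate together. They decide nothing about chance. By these, the slope of 0.133 in size was reached in 11 of 100 (highest other 0.194), the 10 interaction lists in 26 of 60 (16), the siRNA correlation of 0.478 in 15 of 100 (0.622) and the 71 genes of the average siRNA contrast in 1 of 60 (1). Splits that keep the pairs together number 10, too few for a share under 0.05. The highest other values there were 0.122 for the slope (1 of 10 as large), 11 for the interaction lists (2 of 10), 0.611 for the siRNA correlation (5 of 10) and 1 for the average siRNA genes (1 of 10). On the means of the pairs 0 genes were called for the average siRNA contrast. For interaction genes the real count of 0 fixed the outcome (60 of 60, highest other 1), so their regroupings decide nothing.

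For mix, too, 10 splits are too few for a share under 0.05. The real counts of 1391 genes and 22 lists under control siRNA compare with 1 and 19 at most in another split. Under PHGDH siRNA 1291 genes and 20 lists compare with 1043 and 17. The split with 1043 genes set PHGDH-siRNA replicates 1 and 3 and PHGDH-siRNA+Mix replicate 1 against the rest, which points to a structure of the samples whose cause was not tested. With PHGDH-siRNA+Mix replicate 3 in place of its replicate 1 the split called 0 genes, and the blocked model called 3284 for the real grouping. For the correlation of 0.87 between the mix effects, regroupings that swap mix labels within the PHGDH-siRNA pairs gave 1 of 80 as large (highest other 0.686). This argues against a chance allotment of the mix labels, with the pairs taken as given. Whether the arms agree beyond chance given an effect of mix is not decided, because the regroupings remove that effect. Regroupings that part the pairs gave 1 of 100.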

How the results depend on the processing

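The alternatives with replicate 1, 2 or 3 of both PHGDH-siRNA arms left out, the block in those arms, rescaling, voom, the read minimum and all alternatives of the average siRNA contrast were chosen only after the results were seen. DESeq2, its size factors and a filter on library-scaled counts were planned for a count table and not run. Where a value below differs from the reported value, the cause was not tested, but some differences follow from the design. A fit of 6 libraries and a left-out library leave fewer residual degrees of freedom, and no filter adds tested genes. The variance per gene is fitted over all libraries kept, so the replicate 2 pair enters the error of comparisons between control-siRNA libraries too. Precision is limited by 3 libraries per group, and changes of 1.5 fold were mostly out of reach. Of the compared results, 274 of 281 kept direction and side of the threshold with a pseudocount of 0.1, 304 of 362 without a filter, 346 of 362 with the replicate as a block and 209 of 273 in fits of the groups compared. Kept were also 360 of 362 with rescaling, 274 of 281 with voom, 280 of 281 with a minimum of 10 reads, 324 of 362 without the replicate 2 pair, 142 of 144 with the block in the PHGDH-siRNA arms and 1902 of 2268 with 1 library left out. With an estimated correlation only 14 of 81 called lists kept their call, and on the means of same-numbered libraries 0 of 1 result did. The shares pool siRNA, mix and interaction results, called or not, so they do not measure how the siRNA calls held.

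Genes called for PHGDH siRNA without mix (6 reported) numbered 1 without a filter, and that gene was not among the 6. They numbered 0 with the replicate as a block, 0 in the fit of those groups, and 101, 1 and 0 without replicates 2, 1 and 3 of both PHGDH-siRNA arms. With mix (3 reported) they numbered 1 with a pseudocount of 0.1, 5 without a filter (ACOD1 and ARID3B not among them), 0 with the block, 0 in the fit of those groups, 9 with a minimum of 10 reads, and 55 and 0 without replicates 2 and 3 of both arms. For mix under control siRNA (1391) they were 2690 in the fit of those groups, 473 with a 2-fold threshold and 3023 without the replicate 2 pair. Under PHGDH siRNA (1291) they were 761 without a filter, 254 in the fit of those groups, 404 with a 2-fold threshold, 3284 with the block in those arms, and 2190, 481 and 344 without replicates 2, 1 and 3 of both arms. For the interaction (0 genes, 10 lists) no filter gave 5 genes and 5 lists, and the block in the PHGDH-siRNA arms 16 lists. For the average siRNA contrast (71) they were 14 without a filter, 39 with the block, 3 with a 2-fold threshold, 0 with the means of same-numbered libraries (which leaves 4 residual degrees of freedom), and 492, 5 and 2 without replicates 2, 1 and 3 of both arms. The PHGDH change of -1.08 in that contrast lost its call without a filter (adjusted p = 0.056) and with the means of same-numbered libraries (adjusted p = 0.45). Lists called with an estimated correlation were 0 and 0 for siRNA without and with mix, 6 and 8 for mix under control and PHGDH siRNA, and 0 for the interaction. The correlation of the mix effects was 0.733 with a pseudocount of 0.1.

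Among the named genes and the lists called with all libraries, signs that changed without replicate 2 of both PHGDH-siRNA arms were, for PHGDH siRNA without mix, PSPH 0.040, SHMT2 0.24, S100A9 -0.50, LCN2 0.037, KRT10 0.25, glycolysis -0.028, hypoxia -0.0205 and, by the direction of camera, basal keratinocyte genes at a median of 0.052. With mix they were the serine synthesis and folate cycle list at a median of 0.0371, PSPH 0.10, SHMT2 0.19, ATF4 0.23, DEFB4A 0.12, LCN2 0.013 and KRT16 -0.51, and for mix under PHGDH siRNA ATF4 0.032. None of the genes named here was called with or without the pair.

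With 1 library left out at a time, genes called ranged from 0 to 4 for siRNA without mix and from 0 to 6 with mix. They ranged from 658 (without Control-siRNA+Mix replicate 3) to 1223 for mix under control siRNA and from 665 (without PHGDH-siRNA replicate 3) to 1644 (without PHGDH-siRNA replicate 2) under PHGDH siRNA. Lists called for the interaction ranged from 5 to 14. For the average siRNA contrast 2 (without Control-siRNA+Mix replicate 2) to 96 genes (without PHGDH-siRNA+Mix replicate 2) were called, and PHGDH lay between -1.18 and -1.002. Uncalled panel genes changed sign within these ranges. For siRNA without mix these were PSPH -0.59 to 0.040, SHMT2 -0.24 to 0.24, S100A8 -0.40 to 0.075, S100A9 -0.50 to 0.38, LCN2 -0.19 to 0.14, KRT10 -0.58 to 0.25 and MKI67 -0.47 to 0.16. With mix they were PSPH -0.60 to 0.10, SHMT2 -0.53 to 0.19, MTHFD2 -0.30 to 0.42, ATF4 -0.43 to 0.23, DEFB4A -1.31 to 0.12, LCN2 -0.96 to 0.013, KRT16 -0.51 to 0.81, IVL -0.13 to 0.16 and MKI67 -0.90 to 0.22. For mix under control siRNA KRT10 ranged from -0.38 to 0.036. Under PHGDH siRNA they were PSAT1 -0.56 to 0.37, PSPH -0.75 to 0.064, SHMT2 -0.23 to 0.49, MTHFD2 -0.093 to 0.62, ATF4 -0.34 to 0.32, KRT10 -0.75 to 0.13 and MKI67 -1.09 to 0.025. Called lists whose median changed sign were, for siRNA without mix, glycolysis (-0.028 to 0.266), hypoxia (-0.0205 to 0.348) and nuclear oxidative phosphorylation (-0.248 to 0.00989). With mix they were serine synthesis and folate cycle genes (-0.225 to 0.0371) and antimicrobial peptides (-0.594 to 0.0672), and for mix under PHGDH siRNA ribosomal proteins (-0.281 to 0.0291). For the interaction they were NRF2 and glutathione genes (-0.0498 to 0.201), stress keratins (-0.496 to 0.0281), G2/M (-0.404 to 0.0198), hypoxia (-0.323 to 0.016) and immediate early genes (-0.465 to 0.0488).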

Other observations

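In this part the fit on gene length and GC content was planned, and all other tests and the contrast averaged over both mix conditions were chosen only after the results were seen.

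The genes in this paragraph were picked after their values were seen from the 71 called for the average over both mix conditions, and none was called on the means of same-numbered libraries, so they are given as values only. PLAU, the urokinase gene, rose from 84.6 to 156 FPKM without mix and from 369 to 682 FPKM with mix (log2 fold change 0.86, SE 0.151, adjusted p = 0.042), and its receptor PLAUR from 8.86 to 14.6 and from 26 to 38.5 FPKM (0.60, adjusted p = 0.0271). TGFA, a ligand of the EGF receptor, rose from 14.8 to 24.9 and from 41.4 to 60.2 FPKM (0.61, adjusted p = 0.0297). PDCD1LG2, which encodes the checkpoint ligand PD-L2, rose from 0.341 to 1.12 and from 2.72 to 5.6 FPKM (0.73, adjusted p = 0.0376). IL36RN, the antagonist of the IL-36 receptor, rose from 0.774 to 1.45 and from 0.88 to 1.82 FPKM (0.52, adjusted p = 0.0307). ORMDL3, a regulator of sphingolipid synthesis, fell from 16 to 9.03 and from 18.4 to 11 FPKM (-0.73, adjusted p = 0.0285). S100A7 was at 0.661 against 0.922 FPKM without mix, where the groups overlapped, and at 137 against 358 FPKM with mix, where they did not (-0.81, adjusted p = 0.0459).

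Replicate 2 of PHGDH-siRNA and of PHGDH-siRNA+Mix differed from the other libraries of their groups in the same genes, of which those with large differences were picked after the values were seen. AREG, a ligand of the EGF receptor, was at 12.4 FPKM against a mean of 99.5 in the other libraries of the group without mix and at 26.2 against 426 with mix. CHAC1, which degrades glutathione, was at 2.68 against 44.7 and at 3.33 against 57.8 FPKM, and NNMT, a nicotinamide methyltransferase, at 0.0179 against 7.82 and at 0.852 against 53.5 FPKM. LGALS7B, a galectin of stratified epithelium, was at 85.5 against 7.82 and at 85.7 against 1.52 FPKM. CRABP2, which binds retinoic acid, was at 43 against 1.91 and at 35.7 against 2.29 FPKM, and the water channel AQP3 at 62 against 5.13 and at 49.3 against 2.56 FPKM. RCSD1 was at 0.0273 and 0.0756 FPKM in this pair and at 7.43 to 10.7 FPKM in the other 10 libraries, and OR51B5 at 0.0394 and 0.0136 against 5.01 to 7.54 FPKM. At 5 FPKM or more in both and under 0.5 FPKM in each of the other 10 libraries, 0 genes were found. SPARC, outside those limits, was at 15.4 against 0.43 and at 7.09 against 0.0711 FPKM.

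The deviations of these libraries from their groups had r = 0.775 across genes, against 0.0456 between the replicate 2 libraries of the control arms. Cells of the 4 types looked for are argued against, since no marker was above 2.34 FPKM (LAPTM5) in either library and 1 of 49 markers reached 1 FPKM in both libraries and was above each of the other 10. A control-siRNA library in place of a PHGDH-siRNA one is argued against as well, because PHGDH stood at no more than 0.55 times the lowest control-siRNA library. This holds only if the deviation of the pair did not itself lower PHGDH, which was not tested. Serine synthesis and folate cycle genes were lower in both libraries for 10 of 18 members and higher in both for 5. Gene length and GC content took 10.6% of the variance of the deviation, so a part in it stays open. No biological explanation was tested, since the labels name no difference between replicates, and a separate culture or batch of cells could not be tested.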
